A study of Mus musculus with 12 samples.

How the data were processed

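RNA was sequenced from 12 libraries of sorted bone marrow neutrophils in 4 groups of 3, by genotype label and by G-CSF. Per the labels' protocols, cells were sorted, kept for 8 h with or without 10 ng/ml G-CSF, and total RNA was isolated with Trizol; library construction was done by a commercial provider. Groups were taken from the sample titles except for 3 libraries. The titles of the 3 LysMcre-labelled G-CSF libraries name LysMcre, G-CSF and untreated, and do not name Socs3fl/fl. These libraries were placed by their description, which names a Socs3 knockout and G-CSF. The column of LysMcre-labelled untreated replicate 2 carries the number 3, and the title's number was used.

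The deposited values are a signal unit, gene counts divided by 1 size factor per library; they are called normalized counts here. That the authors made them this way was read from the values: each deposited value is a whole multiple of its library's step, and the steps equal median-of-ratios size factors recomputed from the recovered reads to within 1.3e-11. Whole reads were recovered for 100.0% of values at a tolerance of 0.01 read. The genome build is mm10, per the submitters' processing notes. The aligner, counter, annotation and strand setting are not given in the sources used here, so overlapping, antisense and near-identical genes are uncertain. The lowest row total was 121 reads over the 12 libraries, and rows with fewer reads are not analysed here. The table had 13935 rows and 2 columns without a sample or values. Spreadsheet conversion had turned 17 gene names into dates, and 2 of these rows share a name. Gene positions come from the GENCODE mouse release M21 annotation of the same build, which matched 13541 symbols and not 394.

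Depth was 19495754 to 26472118 recovered reads per library, and 3 reads were worth 2.57 to 3.54 normalized counts. Replicate pairs differed by more than sampling noise, with a chi-square per row of 3.5 to 12.47, so all 12 libraries were counted.

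The design written before the data were examined assumed normalized counts that are not whole reads; whole reads could be recovered, so count tests were run beside limma, which stayed the main test. Values were taken as log2(value + 1), rows with a mean under 10 over all libraries were left out (20 rows), and all 4 groups were fitted together in limma 3.58.1 under R 4.3.3 with a trended prior (8 residual degrees of freedom). P-values are two-sided with Benjamini-Hochberg adjustment over 13915 genes and a threshold of 0.05. Fold changes are on the log2(value + 1) scale and understate changes of low genes. The 5 contrasts were genotype without and with G-CSF, G-CSF in each genotype, and their interaction.

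Named genes followed a rule fixed beforehand: Socs3 and Lyz2; per contrast the 8 largest rises and 8 largest falls among genes past 0.05 whose groups did not overlap (6 and 6 for the interaction, without that condition), with a mean of at least 50 in the higher group; and up to 4 members per list, with all oxidase genes in the genotype contrasts. Numbered predicted genes, Riken clones, microRNAs, small nucleolar, mitochondrial, pseudogene and immunoglobulin segment names were left out. Chance alone leaves 3 against 3 libraries without overlap in a share of 0.1. The 24 gene lists, 15 of pathways and 9 of markers, were fixed beforehand and tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, which asks whether a list's genes move one way and compares it with no other gene. Median, mean and test differed in sign for 3, 3, 3, 2 and 3 lists in the 5 contrasts, none of them past 0.05 in camera, while fry called the progenitor markers with G-CSF in floxed (adjusted p = 0.000572) and LysMcre-labelled libraries (9.77e-05): apoptosis regulators, B cell and stroma markers; T and NK cell, eosinophil and dendritic cell markers; eosinophil, progenitor and stroma markers; progenitor and platelet markers; and interferon genes with progenitor and platelet markers.

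The scripts were tested on simulated reads of 13915 genes with 200 changed genes per contrast. For the untreated genotype contrast limma recovered 28% of genes changed 1.25-fold, 56% at 1.5-fold, 68% at 2-fold and 100% at 4-fold, and 6% of its calls were false. For genotype with G-CSF these shares were 24%, 54%, 76% and 98%, for G-CSF in floxed libraries 28%, 58%, 72% and 100%, and in LysMcre-labelled libraries 22%, 60%, 80% and 96%; 8%, 3.7% and 3.7% of calls were false. For the interaction these shares were 8%, 32%, 70% and 88%, and 5.7% of its calls were false. In the data, 3112 to 8717 genes passed in the contrasts that involve G-CSF, far more than the 200 simulated. The simulated shares need not hold for those contrasts. For the genotype contrast with G-CSF, a list of 15 genes raised 1.5-fold was called in 50 of 50 simulations and 0 of 1150 unchanged lists were. The simulated genes varied independently of each other, so this does not test lists whose members vary together, as those of several real lists did. A simulated slope of 1.4 came back as 1.39.

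Alternatives covered the pseudocount, the filter, scaling, the samples in the fit, moderation, sample weights, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, a replicate block, each library left out and a 2-fold threshold. On the recovered reads edgeR called 13, 5097, 6897, 8734 and 3217 genes in the 5 contrasts and DESeq2 28, 4733, 6495, 8363 and 3043. Thinned reads, and the alternatives for the slope other than its gene set, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.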

Results

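Gene expression was measured in neutrophils sorted from mouse bone marrow as cells carrying CD45, CD11b and Ly6G. The cells came from Socs3fl/fl mice, whose Socs3 gene is flanked by loxP sites, or from LysMcre Socs3fl/fl mice, in which a Cre recombinase expressed from the lysozyme 2 locus is meant to delete it in myeloid cells. Socs3 encodes a feedback inhibitor of cytokine signalling through STAT3, and granulocyte colony-stimulating factor (G-CSF) is a cytokine that signals through that pathway in neutrophils. Cells of each genotype were kept for 8 h without addition or with 10 ng/ml G-CSF, giving 4 groups of 3 libraries. The title of the series places the work in a study of brain-targeted autoimmune encephalomyelitis, neutrophil activation and reactive oxygen species. The table held 13935 rows, of which 13915 were tested. No label says whether the 3 libraries of a group came from separate mice, so the p-values measure the spread between these libraries, which may be technical.

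The targeted gene was read first, in every library. Socs3 (ENSMUSG00000053113.3, mm10 chromosome 11, 117966079 to 117970047, minus strand) was not lower in the libraries with a LysMcre label. Without G-CSF it stood at 224.6 ± 23.1 normalized counts (SD, n = 3) in Socs3fl/fl libraries and at 292.4 ± 34.5 (SD, n = 3) in LysMcre-labelled libraries, a log2 difference of 0.38 with a limma adjusted p of 0.329. With G-CSF it stood at 19500 ± 1635 and 37340 ± 1219 normalized counts (SD, n = 3 each), 1.92-fold higher in the LysMcre-labelled libraries (log2 0.94, SE 0.09, limma adjusted p = 1.06e-06). The lowest LysMcre-labelled library with G-CSF, at 35980, lay above the highest Socs3fl/fl library, at 21390. A value per gene does not show which exons were read, so these counts cannot tell a full transcript from one that lacks the floxed part. The Socs3 counts therefore neither show nor exclude the deletion that the genotype label names. For the LysMcre libraries with G-CSF the titles leave out Socs3fl/fl, and only the descriptions name a Socs3 knockout. Every direction below is drawn between libraries with a LysMcre label, called LysMcre-labelled, and libraries labelled Socs3fl/fl alone, called floxed.

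Lyz2 (ENSMUSG00000069516.8; chromosome 10, 117277331 to 117282321), the gene whose locus carries the Cre, separated the genotypes in all 12 libraries. It stood at 222600 ± 3235 normalized counts (SD, n = 3) in floxed and 6053 ± 493 (SD, n = 3) in LysMcre-labelled libraries without G-CSF. With G-CSF the levels were 46230 ± 2464 and 569.3 ± 64.8 (SD, n = 3 each), 81.3-fold lower in the LysMcre-labelled libraries.

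**Figure D1:**
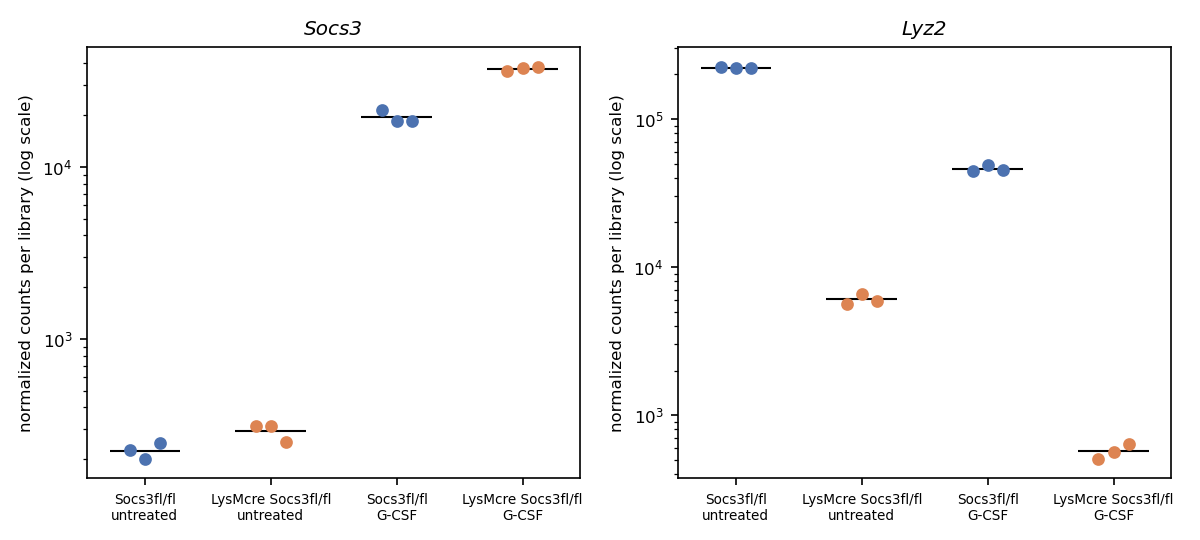
Normalized counts of Socs3 and Lyz2 in each of the 12 libraries on a log scale, by genotype label and treatment; points are libraries and lines are means of 3. Socs3 is higher in the LysMcre-labelled libraries with G-CSF (means 37340 and 19500), while Lyz2 is lower in them under both treatments.

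The first comparison asked which genes differed between the genotypes before stimulation. Few did. Besides Lyz2, Lyz1 stood at 2062 ± 91.4 normalized counts (SD, n = 3) in floxed and 330.6 ± 98.9 in LysMcre-labelled libraries; it is a paralog and neighbour of Lyz2 (chromosome 10, 117287797 to 117292868), so its value is uncertain where reads of the 2 genes can be exchanged. Nfatc1, a calcium-regulated transcription factor, was 1.98-fold higher in the LysMcre-labelled libraries, at 4535 ± 191 against 2296 ± 104 normalized counts (SD, n = 3). Wdfy1 was 1.69-fold higher (log2 0.76, SE 0.08) and Nnt, the mitochondrial proton-pumping transhydrogenase, 1.71-fold higher (log2 0.77, SE 0.14). Mdm1 and the metalloreductase Steap4 were also higher, with log2 differences of 0.66 and 0.61 (SE 0.11 and 0.07). Nnt lost its call in 13 of the alternatives, Mdm1 in 6, and Lyz1 and Steap4 in 2 each. Dynlt1b (chromosome 17, 6430112 to 6436296) was 2.84-fold lower and Fam46c 1.91-fold lower. In all, 16 genes passed 0.05 in limma, 9 higher and 7 lower, and 465 had an unadjusted p under 0.05. The genes outside the naming rule were Igkv8-30 (log2 3.06), Ighg2b (2.36), Ahr (0.60), Gm42868 (-1.73), Gm12474 (-2.20), Tmem181b-ps (-1.48) and Nos2, at 4.49 against 1.27 normalized counts; they are named after their values were seen, because the count is small. Gm42868 lies inside Gm12474 (chromosome 3, 100489664 to 100523920), so the values of both are uncertain. DESeq2 on the recovered reads called 28 genes and shared 14 with limma, and without floxed untreated replicate 1 the limma count was 9. Without LysMcre-labelled untreated replicate 1 it was 10.

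None of the members of the 24 fixed gene lists passed 0.05 without G-CSF in limma over all genes. Adjusted over the list alone, 1 inflammatory gene and 1 eosinophil, basophil and mast cell marker passed. The subunits of the phagocyte NADPH oxidase, the enzyme that makes superoxide, had log2 differences between -0.16 for Cybb and 0.00 for Rac2, and none passed. The member nearest to the threshold among the inflammatory genes was the chemokine Ccl4 (log2 0.63, SE 0.16, limma adjusted p = 0.554). In camera with its preset correlation, 7 of 24 lists passed 0.05. The interferon-stimulated list had a median of -0.52 and a camera adjusted p of 3.58e-12, but the adjusted p was 0.402 with an estimated correlation; its members varied together between libraries, with an estimated correlation of 0.78. Late granule genes (median -0.11, camera adjusted p = 0.0126), NF-kappaB feedback genes (-0.08, 0.0126) and proliferation genes (-0.06, 0.0286) lay lower; their adjusted p = 0.61, 0.57 and 0.61 with an estimated correlation. The direction turned for late granule genes under quantile normalization (adjusted p = 0.999) and for proliferation genes without floxed untreated replicate 1 (adjusted p = 0.801). Inflammatory genes (median 0.16, camera adjusted p = 0.0366), eosinophil, basophil and mast cell markers (0.30, 0.0194) and dendritic cell markers (0.23, 0.0194) lay higher; each had an adjusted p = 0.352 with an estimated correlation. The interferon call was also lost without floxed untreated replicate 3, and the other 6 calls were lost in 3 to 12 of the alternatives. No list passed in fry, which tests the direction of a list on balance and does not compare it with other genes. In none of the 5 comparisons did a list call hold with an estimated correlation.

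The second comparison asked how the genotypes differed with G-CSF. Genes of chemokines, a growth factor, enzymes and a motor protein were among those highest above the floxed level in the LysMcre-labelled libraries. The neutrophil-attracting chemokines Cxcl3 and Cxcl2 stood at 5101 ± 730 and 13340 ± 1793 normalized counts against 195.9 ± 32.6 and 1578 ± 337 in floxed libraries (SD, n = 3), with log2 differences of 4.70 and 3.09 (SE 0.18 and 0.19). Csf1, the macrophage growth factor, was 8.01-fold higher and the matrix metalloproteinase Mmp19 18.5-fold higher. Kif1a, Ppm1j, Sphk1, which makes sphingosine 1-phosphate, and Pla1a were 13.7-fold, 12.3-fold, 11.0-fold and 8.77-fold higher. Among the genes that were lower were Lyz2, Lyz1 and the homeobox gene Lhx1 (29.8 ± 3.36 against 167.6 ± 23.1; SD, n = 3). Mgst2 (log2 -2.23, SE 0.12), Dnah6 (-2.39, SE 0.17), Ifit1bl2 (-2.23, SE 0.10) and Adgrg5 (-2.34, SE 0.70) were lower as well; Adgrg5 lost its call in 5 of the alternatives, 2 of them without LysMcre-labelled G-CSF replicate 1 or 2. In limma, 5013 of 13915 genes passed 0.05, 2379 higher and 2634 lower, and 830 of them differed at least 2-fold. With every library scaled to an equal total the median of all genes moved to -0.13 and 28.2% of the calls were higher, against 47.5% in the main test.

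The NADPH oxidase genes were mostly lower in the LysMcre-labelled libraries with G-CSF. Cybb, the catalytic subunit, stood at 11610 ± 1200 against 23000 ± 1501 normalized counts (SD, n = 3; log2 -0.99, SE 0.09), and the cytosolic activator Ncf1 at 20160 ± 2758 against 32570 ± 3167 (log2 -0.70, SE 0.10). The proton channel Hvcn1 (log2 -0.58), Ncf4 (-0.35) and the GTPase Rac2 (-0.21) were lower, while Rac1 was higher (0.25). Cyba (-0.17) did not pass, with a limma adjusted p of 0.0682. Of 8 measured members 5 were lower, 1 was higher and 2 did not pass; adjusted over the list alone, 7 were lower and 1 higher. The list test gave an adjusted p of 0.0151, and an adjusted p of 0.39 with an estimated correlation. Rac2 lost its call in 12 of the alternatives, and Rac1 under quantile normalization and equal totals.

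**Figure D2:**
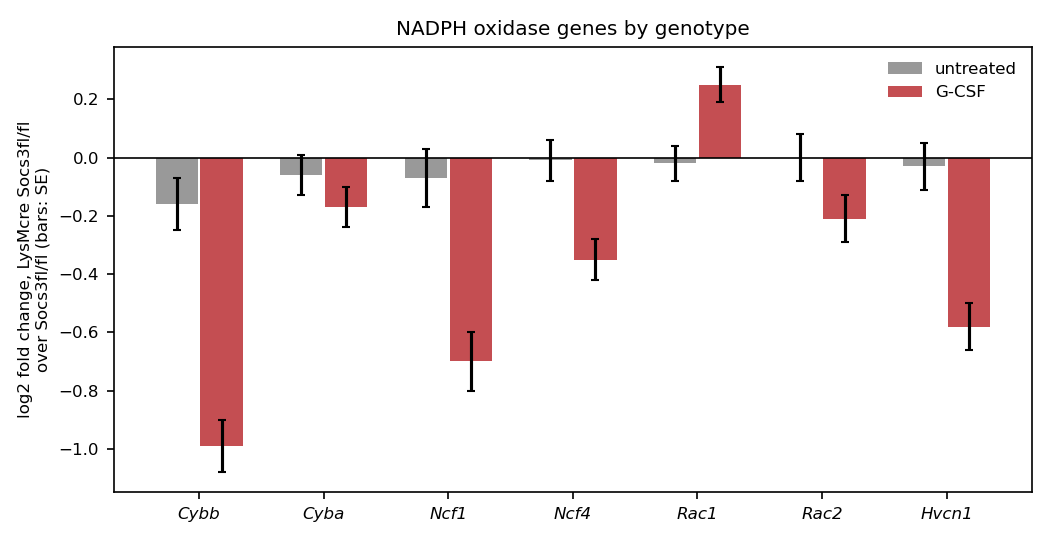
Log2 fold change of 7 NADPH oxidase genes, LysMcre-labelled over floxed, without G-CSF (grey) and with G-CSF (red); bars carry the standard error from limma. Cybb is at -0.16 without and -0.99 with G-CSF, and Rac1 is the member above 0 with G-CSF.

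Antioxidant genes moved both ways. Txnrd1, thioredoxin reductase (log2 1.70, SE 0.05), the cystine transporter Slc7a11 (1.65, SE 0.10) and Gclm, a subunit of the glutathione-making ligase (0.90, SE 0.09), were higher, and the glutathione peroxidase Gpx1 was lower (-0.85, SE 0.07). Of 18 members 10 were higher and 4 lower, or 10 and 5 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.0589) but passed fry (adjusted p = 0.000398). Cytokine-induced STAT target genes were higher in 11 of 14 members and lower in 1, with the same counts adjusted over the list alone: the cytokine feedback gene Cish by 2.07, the decoy receptor Il1r2 by 1.70, Socs1 by 1.4 and Il4ra by 1.14 on the log2 scale (camera adjusted p = 8.24e-07, and adjusted p = 0.203 with an estimated correlation). Inflammatory cytokines and chemokines were higher in 9 of 19 measured members and lower in 1, or 10 and 1 adjusted over the list alone; Ccl4 was at log2 2.82 and Il1rn, the interleukin 1 receptor antagonist, at 1.58 (camera adjusted p = 4.07e-05, and adjusted p = 0.115 with an estimated correlation). NF-kappaB feedback genes were higher in 10 of 12 members, or 11 adjusted over the list alone, among them Nfkbia (0.67) and Nfkb1 (0.63), with an adjusted p of 4.4e-06 and an adjusted p of 0.349 with an estimated correlation.

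Genes of granules that form late in neutrophil development were lower in 12 of 15 measured members and higher in 1, also when adjusted over the list alone. Pglyrp1, a bactericidal granule protein, fell below the floxed level by 1.38 on the log2 scale, at 8922 ± 562 against 23270 ± 2356 normalized counts (SD, n = 3); Anxa1 was at -0.85, Itgb2l at -0.75 and the collagenase Mmp8 at -0.56. The list test gave an adjusted p of 7.72e-05, and an adjusted p of 0.397 with an estimated correlation. Of 7 primary granule genes Prss57 alone passed (log2 -1.15), also when adjusted over the list alone (camera adjusted p = 0.427). Glycolysis genes were higher in 13 of 18 members and lower in 4, with the same counts adjusted over the list alone: Pfkp (1.28), the glucose transporter Slc2a1 (1.14) and Pfkl (1.03) were higher and the transporter Slc2a3 was lower (-1.17). The adjusted p was 0.000329, and the adjusted p was 0.39 with an estimated correlation. Nucleolar ribosome biogenesis genes were higher in 13 of 17 members, or 16 adjusted over the list alone (Odc1 0.83, Nop58 0.75; adjusted p = 4.07e-05, and adjusted p = 0.39 with an estimated correlation).

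Apoptosis and survival regulators were higher in 8 of 17 members and lower in 2, also when adjusted over the list alone; these include genes of opposite known action, the death-promoting Bcl2l11 (log2 1.77) and Fas (0.91) and the survival genes Bcl2l1 (1.49) and Cflar (0.73). The list test gave an adjusted p of 0.00129, and an adjusted p of 0.115 with an estimated correlation. Stress genes of the endoplasmic reticulum were higher in 7 of 14 members and lower in 1, also when adjusted over the list alone, among them the transcription factor Xbp1 (1.52) and the chaperone Hspa5 (0.58; adjusted p = 0.0125, and adjusted p = 0.349 with an estimated correlation). Cholesterol genes were higher in 8 of 16 members, or 9 adjusted over the list alone, by small amounts (Cyp51 0.34, Insig1 0.29; adjusted p = 0.0197, and adjusted p = 0.39 with an estimated correlation), and the list call was also lost under quantile normalization, equal totals and DESeq2. Surface receptors were higher in 10 of 21 members and lower in 4, or 13 and 4 adjusted over the list alone; the lipopolysaccharide receptor Tlr4 was at 0.92 and the marrow-retention receptor Cxcr4 at -0.53 (adjusted p = 0.0197, and adjusted p = 0.397 with an estimated correlation), a call also lost under quantile normalization, equal totals and without floxed G-CSF replicate 3. Interferon-stimulated genes were lower in 8 of 25 measured members and higher in 2, or 9 and 2 adjusted over the list alone: Cmpk2 was at -1.94, Ifit3 at -1.88, Ifit2 at -1.48 and Irf1 at 0.39 (camera adjusted p = 0.0516). Proliferation genes passed in 1 of 19 members, Tk1 (-0.26), and in none adjusted over the list alone (adjusted p = 0.806); Tk1 lost its call in 11 of the alternatives.

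Markers of other cells were measured beside these groups. With G-CSF, the median log2 difference between genotypes was -0.12 for B cells, 0.03 for T and NK cells, -0.12 for monocytes, 0.05 for eosinophils, basophils and mast cells and -0.36 for erythroid cells. It was 0.26 for progenitors, 0.03 for dendritic cells, 0.44 for stroma and endothelium and 0.26 for platelets. Without G-CSF the medians were -0.06, 0.28, 0.09, 0.30, -0.18, 0.16, 0.23, 0.15 and 0.08 in the same order. With G-CSF, Kit (log2 1.07), Pecam1 (0.92) and Col1a1 (1.12) were higher and Ly6c2 (-1.11) was lower. The monocyte markers went both ways, as 1 of 9 passed higher and 1, Ly6c2, lower. Ighm (0.80), Cd34 (0.39), Cd3d (-0.47), Nkg7 (-0.67) and Myb (-0.34) also passed and lost their call in some alternatives. No marker list passed camera in this comparison. Fry, which does not compare a list with other genes, called the progenitor (adjusted p = 0.000879) and the stroma and endothelium markers (0.00394).

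The third comparison asked what G-CSF changed in floxed neutrophils. The largest rises were in genes that were low beforehand. Steap4 went from 55.5 ± 5.33 to 18810 ± 1200 normalized counts, the endothelial lipase Lipg from 22.8 ± 6.42 to 14020 ± 1462, the transglutaminase Tgm1 from 54.1 ± 2.20 to 11080 ± 1106 and the secreted inhibitor Wfdc17 from 140.6 ± 25.9 to 43570 ± 3730 (SD, n = 3 each). Nos2, the inducible nitric oxide synthase, reached 1767 ± 112 from 1.27 ± 0.54, a level near that of 1 read per library, so its fold change is not given. Igfbp6, Sult6b2 and Wfdc18 also rose, to means of 2162, 603.5 and 238.7. Socs3 rose by 6.44 on the log2 scale. Krt83 (799.7 to 25.5), Sntb1 (843 to 37.6), Itih5 (1177 to 59.9), Acot1, Lct, Tgm3, Lyve1 and Ascl2 had the largest falls. In limma 6784 genes passed 0.05, 3360 higher and 3424 lower, and 1980 changed at least 2-fold. With equal totals 38.5% of the calls were higher, against 49.5%, and the median of all genes was -0.09.

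By list, 12 of 14 STAT target genes rose in floxed cells, led by Il4ra (log2 3.54), Bcl3 (3.42), Junb (2.91) and Pim1 (2.86), and all 12 also passed adjusted over the list alone (camera adjusted p = 2.64e-09, and adjusted p = 0.0997 with an estimated correlation). Cholesterol genes rose in 15 of 16 members (Fdps 1.33, Lss 1.28) and ribosome biogenesis genes in 14 of 17 (Srm 2.58, Nop58 1.58), with 15 in each list adjusted over the list alone; camera adjusted p was 4.56e-08 and 3.67e-05, and adjusted p = 0.0759 and 0.452 with an estimated correlation. Inflammatory genes rose in 12 of 19 (Ccl4 5.47, Cxcl3 4.69, Osm 2.15; 12 adjusted over the list alone; adjusted p = 5.45e-05, and adjusted p = 0.0861 with an estimated correlation). Endoplasmic reticulum stress genes rose in 10 of 14 (Xbp1 2.04; 11 higher and 1 lower adjusted over the list alone), proliferation genes in 16 of 19 with 1 lower (Mcm4 0.90, Tk1 -0.96; the same adjusted over the list alone) and NF-kappaB feedback genes in 9 of 12 (Birc3 1.22; 9 adjusted over the list alone). Their camera adjusted p were 0.000179, 0.000472 and 0.001, and adjusted p = 0.106, 0.452 and 0.452 with an estimated correlation.

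Surface receptors rose in 13 of 21 and fell in 6, also adjusted over the list alone: Csf2rb, a receptor chain shared by interleukin 3 family cytokines, rose by 2.70 and Tlr4 by 2.44, and Cxcr4 fell by 2.50 on the log2 scale. Interferon-stimulated genes rose in 17 of 25 and fell in 2 (Gbp2 3.04, Oasl2 1.80; 18 and 2 adjusted over the list alone). Their camera adjusted p were 0.001 and 0.00109, and adjusted p = 0.384 and 0.727 with an estimated correlation; DESeq2 statistics ended the interferon call. The other lists did not pass camera. NADPH oxidase genes fell in 4 of 8 and rose in 2 (Hvcn1 -1.93, Ncf1 -1.07, Cybb -0.90; the same adjusted over the list alone; adjusted p = 0.19). Antioxidant genes rose in 8 of 18 and fell in 4 (Gclm 1.67, Prdx6 -0.96; the same adjusted over the list alone; adjusted p = 0.307). Primary granule genes rose in 5 of 7 and fell in 1 (Ctsc 2.02, Prtn3 1.37; the same adjusted over the list alone; adjusted p = 0.0762), and late granule genes fell in 7 of 15 and rose in 2 (Ltf -1.74, Camp -1.60, Hp 1.23; adjusted p = 0.134), or 8 and 2 adjusted over the list alone. Glycolysis genes rose in 7 of 18 and fell in 6 (Slc2a1 3.92, Pfkfb3 1.60; adjusted p = 0.552), and apoptosis genes rose in 6 of 17 and fell in 4 (Bcl2l1 1.60, Mcl1 1.54, Bbc3 -1.35; adjusted p = 0.191), with the same counts adjusted over the list alone. Marker medians were -0.20 for B cells, -0.06 for T and NK cells, 0.32 for monocytes, 0.08 for eosinophils, basophils and mast cells, -0.74 for erythroid cells, -0.10 for progenitors, -0.06 for dendritic cells, 0.14 for stroma and -0.24 for platelets. Members of these lists went both ways: 5 of 9 monocyte markers rose and 2 fell (Ccr2 0.75, Ly6c2 -1.18), Siglecf (1.77) and Kit (1.90) rose, and Ear2 (-3.17), Cd3d (-2.23), Col1a1 (-2.05) and Myb (-0.78) fell. Of the lists that did not pass camera, fry called the NADPH oxidase (adjusted p = 9.76e-05), antioxidant (0.000688), primary granule (0.00649), apoptosis (9.74e-05) and glycolysis genes (0.000296) and the T and NK cell (0.000752) and progenitor markers (0.000572). These values do not separate a change in other cells from a change in the sorted neutrophils.

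The fourth comparison asked the same of LysMcre-labelled neutrophils. Lipg rose from 17.5 ± 4.93 to 18990 ± 1260 normalized counts, Tgm1 from 57.0 ± 10.1 to 39340 ± 2326, Steap4 from 84.9 ± 5.41 to 35130 ± 1427 and Wfdc17 from 229.1 ± 39.8 to 71900 ± 3676 (SD, n = 3 each). Cxcl3 rose from 8.39 ± 1.05 to 5101 ± 730, Entpd3 from 66.0 to 22430, Sult6b2 from 2.54 to 1755 and Nos2 from 4.49 ± 1.58 to 7766 ± 1395. Nat8l fell from 3548 to 49.0, and Tgm3, Sstr4, Lct, Ascl2, Aplnr, Faim2 and Has2 fell to means of 3.04 or less, at or under the value of 3 reads in a library. In limma 8717 genes passed 0.05, 4325 higher and 4392 lower, and 3435 changed at least 2-fold. With equal totals 31.2% of the calls were higher, against 49.6%, and the median of all genes was -0.26.

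By list, STAT target genes rose in 12 of 14 and fell in 1 (Il4ra 4.70, Il1r2 4.39; the same adjusted over the list alone; camera adjusted p = 3.87e-07, and adjusted p = 0.137 with an estimated correlation). Cholesterol genes rose in 15 of 16 (Sqle 1.4; 16 adjusted over the list alone), ribosome biogenesis genes in 16 of 17 (Nop58 2.31; 16) and NF-kappaB feedback genes in 12 of 12 (Birc3 1.72; 12), with camera adjusted p of 7.54e-07, 8.53e-06 and 8.53e-06 and adjusted p = 0.0807, 0.316 and 0.271 with an estimated correlation. Inflammatory genes rose in 13 of 19 and fell in 1 (Ccl4 7.67, Cxcl2 6.34; 14 and 1 adjusted over the list alone; adjusted p = 3.37e-05, and adjusted p = 0.0807 with an estimated correlation). Stress genes of the endoplasmic reticulum rose in 11 of 14 and fell in 1 (Xbp1 3.44), surface receptors rose in 15 of 21 and fell in 5 (Tlr4 3.43, Cxcr4 -3.04) and proliferation genes rose in 14 of 19 and fell in 1 (Mcm2 1.16), with the same counts adjusted over the list alone. Their camera adjusted p were 0.000692, 0.00105 and 0.00461, and adjusted p = 0.137, 0.271 and 0.561 with an estimated correlation.

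Late granule genes fell in 10 of 15 and rose in 2 in the LysMcre-labelled libraries (Ltf -2.56, Camp -2.53; 11 and 2 adjusted over the list alone; camera adjusted p = 0.0094, and adjusted p = 0.649 with an estimated correlation). Apoptosis genes rose in 10 of 17 and fell in 2 (Bcl2l1 3.06, Bcl2l11 2.40), interferon-stimulated genes rose in 15 of 25 and fell in 4 (Gbp2 3.09, Cmpk2 -2.91) and glycolysis genes rose in 12 of 18 and fell in 5 (Slc2a1 5.01, Pfkfb3 2.73), with the same counts adjusted over the list alone. Their camera adjusted p were 0.0123, 0.0189 and 0.0307, and adjusted p = 0.137, 0.842 and 0.649 with an estimated correlation. DESeq2 statistics ended the interferon and proliferation calls, and quantile normalization and a mean of at least 50 the glycolysis call. NADPH oxidase genes fell in 5 of 8 and rose in 1 (Hvcn1 -2.48, Cybb -1.73, Ncf1 -1.70, Rac1 0.45; adjusted p = 0.0507), antioxidant genes rose in 9 of 18 and fell in 8 (Slc7a11 3.48, Txnrd1 3.07; adjusted p = 0.47) and primary granule genes rose in 4 of 7 and fell in 1 (Ctsc 2.24, Prss57 -1.75; adjusted p = 0.47), with the same counts adjusted over the list alone. Marker medians were -0.29 for B cells, -0.47 for T and NK cells, 0.39 for monocytes, -0.17 for eosinophils, basophils and mast cells, -1.07 for erythroid cells, -0.19 for progenitors, -0.17 for dendritic cells, 0.19 for stroma and 0.13 for platelets. Of the monocyte markers 3 of 9 rose and 2 fell (Ly6c2 -2.16); Kit (2.95) and Siglecf (1.61) rose, and Ear2 (-3.17), Cd3d (-2.98) and Gp1bb (-1.55) fell. Of the lists that did not pass camera, fry called the NADPH oxidase and antioxidant genes (adjusted p = 2.15e-06 for both) and the T and NK cell (1.29e-05), progenitor (9.77e-05), dendritic cell and stroma markers (0.0169 for both).

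The fifth comparison asked whether the response to G-CSF differed between the genotypes. It did for 3112 genes in limma, with 1513 differences above 0 and 1599 below, and 627 of at least 2-fold. Most genes responded in the same direction in both genotypes and further in the LysMcre-labelled libraries. Of the 9197 genes past 0.05 for the mean effect of G-CSF, 4601 rose and 4596 fell on average. The change was larger in the LysMcre-labelled libraries for 80.7% of those that rose, with a median of 0.74 against 0.49 on the log2 scale, and for 83.1% of those that fell, with a median of -0.77 against -0.50. Across these genes, which are not independent replicates, the responses had a Pearson correlation of 0.938 and a Spearman correlation of 0.94, and orthogonal regression of the LysMcre-labelled on the floxed response had a slope of 1.396. With equal totals 23% of the interaction calls were above 0, against 48.6%, and the median of all genes was -0.18.

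**Figure D3:**
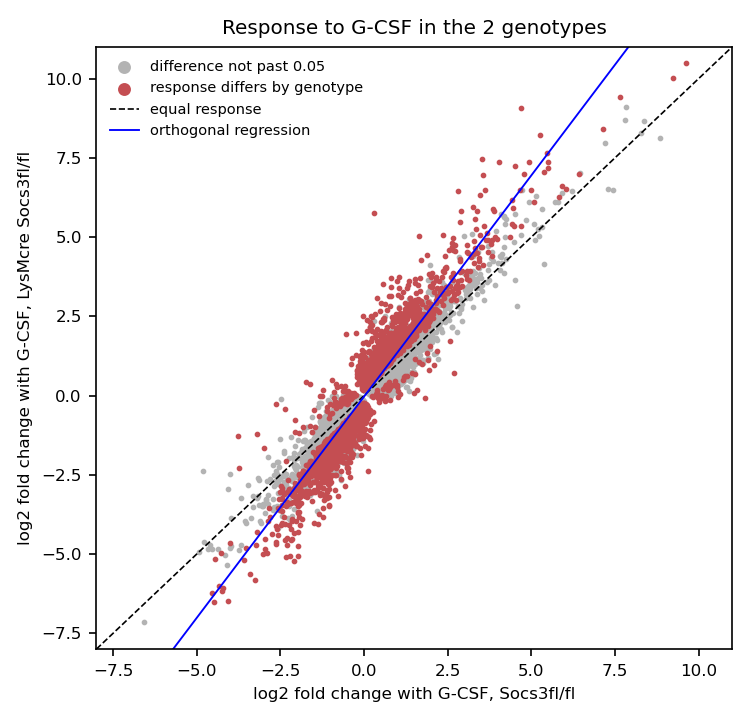
Log2 fold change with G-CSF of the 9197 genes past 0.05 for the mean effect, floxed libraries on the horizontal and LysMcre-labelled libraries on the vertical axis; red points are genes whose response differed by genotype. The points lie along a line of slope 1.396, steeper than the dashed line of equal response.

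The genes with the largest positive differences of the response were Cxcl3 (log2 4.39, SE 0.26), Mmp19 (3.95, SE 0.21), Kif1a (3.64), Pla1a (3.41), Sphk1 (3.39) and Ppm1j (3.35). Those with the largest negative ones were Mmp23 (-2.84), RP24-325N9.4 (-2.78), Aplnr (-2.57), Lhx1 (-2.42, SE 0.19), Sstr4 (-2.42) and Dnah6 (-2.40, SE 0.24). Mmp23, RP24-325N9.4, Aplnr and Sstr4 had means of 1.93 or less in the LysMcre-labelled libraries with G-CSF, and Kif1a (1.57 and 1.91) and Pla1a (3.96 and 2.88) were near the value of 3 reads without it. The values of these 6 genes depend on the pseudocount and are no bound. Among the oxidase genes the response of Cybb (-0.83, SE 0.13), Ncf1 (-0.63, SE 0.14), Hvcn1 (-0.55, SE 0.11) and Ncf4 (-0.33, SE 0.10) differed by genotype. That of Rac1 differed the other way (0.27, SE 0.08), a call lost in 6 of the alternatives.

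By list, 11 of 24 passed camera for the interaction with its preset correlation and 0 with an estimated one. STAT target genes responded more strongly in 10 of 14 members and less in 1 (Cish 2.12, Il1r2 1.97; adjusted p = 2.8e-07, and adjusted p = 0.193 with an estimated correlation), and NF-kappaB feedback genes in 10 of 12 (Nfkbia 0.76, Nfkb1 0.68; adjusted p = 2.8e-07, and adjusted p = 0.273 with an estimated correlation). Inflammatory genes had a positive difference in 8 of 19 (Cxcl2 2.87, Csf1 2.62, Il1rn 1.69; adjusted p = 4.37e-05, and adjusted p = 0.0845 with an estimated correlation). Glycolysis genes had one in 13 of 18 and a negative one in 2 (Pfkfb3 1.13, Pfkl 1.11, Slc2a3 -1.09; adjusted p = 8.68e-05, and adjusted p = 0.378 with an estimated correlation). Adjusted over the list alone these counts were the same.

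Late granule genes had a negative difference in 7 of 15 and a positive one in 1 (Pglyrp1 -1.27, Anxa1 -0.75; adjusted p = 0.000759, and adjusted p = 0.483 with an estimated correlation), and NADPH oxidase genes in 4 of 8 against 1 (adjusted p = 0.0317, and adjusted p = 0.482 with an estimated correlation), with the same counts adjusted over the list alone. Apoptosis regulators had positive differences in 7 of 17 and negative ones in 2, or 8 and 2 adjusted over the list alone (Bcl2l11 1.80, Fas 0.99), ribosome biogenesis genes in 4 of 17 (Odc1 0.78; 4) and cholesterol genes in 7 of 16 (Insig1 0.42; 7). Their adjusted p were 0.000759, 0.000782 and 0.00647, and adjusted p = 0.0845, 0.482 and 0.311 with an estimated correlation. Surface receptors had positive differences in 9 of 21 and negative ones in 3 (Tlr4 0.98, Cxcr4 -0.53; 9 and 3 adjusted over the list alone), and stress genes of the endoplasmic reticulum in 3 of 14 (Xbp1 1.4; 5 and 2 adjusted over the list alone). Their adjusted p were 0.00647 and 0.0317, and adjusted p = 0.378 with an estimated correlation for both; the first call was also lost under quantile normalization, the second in 7 of the alternatives, and that of the NADPH oxidase genes in 4. Fry also called the antioxidant genes (adjusted p = 0.00384; 0.0838 in camera) and the T and NK cell (0.0398; 0.39) and stroma markers (0.0391; 0.238).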

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

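The 3 tests on Socs3, and those of the untreated splits, of the position of the untreated genes and of the B cell markers, were chosen after the result they bear on was seen; the thinned reads and other scalings of the slope are alternatives added after seeing the data.

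The response to G-CSF differed by genotype for 3112 genes, by the interaction term, which is what brings the results of this part forward. The differences were 4.39 for Cxcl3, 3.95 for Mmp19, 3.64 for Kif1a, 3.41 for Pla1a, 3.39 for Sphk1 and 3.35 for Ppm1j on the log2 scale. They were -2.84 for Mmp23, -2.78 for RP24-325N9.4, -2.57 for Aplnr, -2.42 for Lhx1, -2.42 for Sstr4 and -2.4 for Dnah6. By list, the median difference was 0.7 for STAT target genes, -0.27 for NADPH oxidase genes, -0.35 for late granule genes, 0.34 for inflammatory genes and 0.24 for surface receptors. It was 0.66 for NF-kappaB feedback genes, 0.44 for apoptosis regulators, 0.36 for ribosome biogenesis, 0.45 for glycolysis, 0.28 for cholesterol and 0.22 for endoplasmic reticulum stress.

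The larger response in LysMcre-labelled libraries is a pattern for which scaling and depth were tested. Under 3 other scalings the lowest slope was 1.373, and with reads thinned to the shallowest library it was 1.394. Scaling by 1 factor per library shifts all log2 changes of a comparison nearly alike, so it could hardly move the slope. Quantile normalization can move it and left it at 1.373 or more, so only that scaling argues against the normalization as the whole cause. The thinned slope argues against a difference in depth as the whole cause. Genotype was regrouped within treatment in 100 draws: 5 gave as many genes as the real 3112, the real one included, with 3403 the highest other. This count does not exclude chance and is largely set by the design, since 20 of the 200 possible regroupings keep the G-CSF libraries parted by genotype; the 6 of these among the other draws gave 3005 to 3403 genes, and the 93 draws that mixed the libraries gave at most 1. The genotype remains a biological explanation that the design names, and it stays open. The floxed libraries have no LysMcre label, and Lyz2 was far lower in the LysMcre-labelled ones. An effect of Socs3 deletion therefore cannot be told apart from one of the Cre or of the lower Lyz2.

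Socs3 was not lower in the LysMcre-labelled libraries. An exchange of genotype labels is argued against by Lyz2, which lay far below the lowest floxed library of the same treatment in all 6 of them. The fold of 1.92 with G-CSF cannot be told apart from reads on a part of the gene that the deletion leaves or from cells that kept the floxed allele, because a value per gene does not show the exons. The genotype difference of 0.94 lies between the 25th and 75th percentiles of the fixed STAT list (0.42 and 1.11), consistent with raised transcription of such genes, the Socs3 locus among them, as a hypothesis.

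The 16 genes that differed without G-CSF are the third pattern. Of the 15 with a position, 3 lie within 10 Mb of Lyz2 or Socs3 and 12 do not. This argues against inherited sequence next to the engineered loci as the cause for most of them. Lyz1 and Mdm1 stay open, and Lyz2 is itself the gene whose locus carries the Cre. More B cells as the source of Ighg2b and Igkv8-30 are argued against by the 8 B cell markers other than Ighm, with a median of -0.09 and a range of -0.2 to 0.06; Ighm, set aside as an immunoglobulin gene, was itself at 0.59 (unadjusted p = 0.0476), and plasma cells, which lack most of these markers, were not tested and stay open. The split of the 6 libraries into 10 ways is too few for a share under 0.05: 1 split, the real one, gave 16 genes and the highest other gave 1. Dynlt1b and Tmem181b-ps lie side by side on chromosome 17 and Gm42868 lies inside Gm12474. The 12 genes away from both engineered loci are therefore not 12 separate places. Other differences in strain background were not tested.

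For the other contrasts 10 splits are likewise too few. In each, 1 split, the real one, gave the largest count: 5013 against a highest other of 0 for genotype with G-CSF, 6784 against 0 for G-CSF in floxed libraries, and 8717 against 2 in LysMcre-labelled libraries.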

How the results depend on the processing

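All settings below were planned except thinned reads and the alternatives for the slope and correlations other than their gene set. The slope stayed between 1.373 and 1.417 over the scalings and left-out libraries. No named gene changed direction while called. Of the values for named genes under the alternatives, 10550 stayed on the same side of the threshold, called or not, 159 lost a call and 45 gained one; of those for list tests, 3324 stayed on the same side, 107 lost a call, 89 gained one and 3 changed sign. Of the untreated genotype count, 16 became 9 without the trend, 28 with DESeq2, 9 with a 2-fold threshold and 9 to 21 with 1 library left out. The 2-fold threshold gave 830, 1980, 3435 and 627 genes for genotype with G-CSF, G-CSF in floxed, G-CSF in LysMcre-labelled libraries and the interaction, by construction. The lists past 0.05 without G-CSF were 7, and 3 under quantile normalization, 3 under equal totals, 4 to 12 with 1 library left out and 0 with fry; with an estimated correlation they were 0 in all 5 contrasts. In floxed cells fry called 16 lists with G-CSF, against 9. The late granule list changed sign without G-CSF under quantile normalization (adjusted p = 0.999, range 5.89e-06 to 0.999), the proliferation list without floxed untreated replicate 1 (range with 1 library left out 0.000108 to 0.801), and progenitor markers with G-CSF in LysMcre-labelled libraries under fry (9.77e-05, range to 0.994); the cause was not tested. Pearson's correlation of the 2 responses was 0.945 with a mean of at least 50, 0.93 with sample weights and 0.911 over all genes, and Spearman's was 0.927 with equal totals, 0.932 with sample weights and 0.857 over all genes. Their ranges with 1 library left out were 0.931 to 0.938 for Pearson and 0.935 to 0.942 for Spearman.

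Whether equal replicate numbers pair the libraries is not settled. Same-number correlations ran from -0.33 to 0.45, and 7 of 12 libraries matched their own number best. Between untreated and G-CSF libraries they were 0.45, 0.35 and 0.06 in floxed cells. In LysMcre-labelled cells they were 0.29, -0.03 and 0.02. With a replicate block of 3 levels the counts were 16, 4892, 6673, 8692 and 2967, and with a block of 6 levels within genotype 6835, 8861 and 3141 for the last 3 contrasts.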

Other observations

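The test of genes raised on average by G-CSF and the genes with opposite responses were chosen after results were seen.

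Some genes went opposite ways with G-CSF in the 2 genotypes. In limma 6113 genes passed 0.05 in both with the same direction and 67 with opposite directions. Of the 67, 41 fell in floxed and rose in LysMcre-labelled libraries and 26 did the reverse. The interaction passed for all 67, which follows largely from the choice, since opposite changes add up in it. Some changes were small, such as -0.12 and 0.14 for Riok3. With equal totals the median of all genes was -0.09 in floxed and -0.26 in LysMcre-labelled libraries, so such signs can depend on scaling. Nt5e, the ecto-enzyme that makes adenosine from AMP, went from 2459 to 1155 normalized counts in floxed and from 2475 to 4795 in LysMcre-labelled libraries (log2 -1.09 and 0.93, SE 0.11 each). The scaffold gene Mpp7 was at -0.93 and 1.61, the prolyl hydroxylase Egln3 at -0.75 and 0.88, the co-stimulatory ligand Cd80 at -0.36 and 1.2, the adhesion molecule Alcam at -0.96 and 0.49 and the granule membrane protein Cd63 at -0.85 and 0.36. In the other direction, the RNA helicase Mov10 was at 0.59 and -0.58 and the transcription repressor Bcl6 at 0.33 and -0.33. These were chosen after their values were seen.

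A hypothesis was that LysMcre-labelled neutrophils may lie partly toward the G-CSF state before G-CSF is added, since Steap4, Ahr and Nos2 were higher in them and rise with G-CSF, Nos2 from means of only 1.27 and 4.49 normalized counts. Of the 16 genes called without G-CSF, 7 differed in the direction of a G-CSF response that passed in both genotypes: these 3, and Lyz2, Lyz1, Dynlt1b and Tmem181b-ps, which were lower and fall with G-CSF. In 5 the directions were opposite: Nfatc1, Nnt, Wdfy1 and Mdm1 were higher and fall (Nnt 0.77, then -1.22 and -1.94), and Fam46c was lower (-0.94) and rises. In the other 4, Ighg2b, Igkv8-30, Gm42868 and Gm12474, the response did not pass in both genotypes. Lyz2 is the gene that LysMcre is placed in, so its difference does not bear on the hypothesis. The test took the 200 genes that G-CSF raised most in LysMcre-labelled libraries among those with an untreated mean of at least 50. Their median difference between the untreated genotypes was 0.03 on the log2 scale, with 115 of 200 above 0, and the largest size among the other 9 splits of these libraries was 0.06. This decides nothing, because the genes were picked with the untreated LysMcre-labelled libraries that enter the difference, which pulls it down. For the 200 genes that G-CSF raised most on average over both genotypes, a choice that does not favour either untreated group, the median was 0.03 with 113 above 0, and the largest size among the other splits was 0.09. The hypothesis stays open, as 6 libraries do not settle a shift of this size.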
